A study of Mus musculus with 23 samples.

How the data were processed

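Poly(A) RNA of cardiac macrophages (Ly6G-negative, CD11b-positive) was measured in 23 libraries of 6 groups, formed by genotype and time as the labels give them. The deposited count table holds the authors' read counts per gene, whole numbers that were used as they stand, for 54532 genes of which 103 share their name with another gene. The deposited FPKM table holds the authors' FPKM values, and on genes with at least 100 counts it was checked to equal the count divided by gene length and by 1 constant per library that is not the column total. The submitters' processing notes name TopHat2 2.0.9, Cufflinks 2.1.1 and HTSeq 0.6.1 with builds mm10 and GRCm38.p6, without saying which tool made which value, and the labels do not state strandedness. Per library 0.0208 to 0.723% of counts fell on annotated rRNA genes, and the 10 most abundant genes took 6.37 to 9.83%.

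Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM scaling, the filterByExpr low-count filter on the 6 groups, which kept 16545 genes, and robust quasi-likelihood fits with 1 coefficient per group over all 23 libraries. Contrasts were MyS7KO against S7fl/fl at each time, each pair of times within each genotype, and the differences of the genotype effect between times. P-values are two-sided and Benjamini-Hochberg adjusted over all genes tested, and a gene was called at an adjusted p under 0.05. Principal components were taken from the 1000 genes with the highest variance of log2 CPM. No library was left out.

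A set of 30 gene lists, 16 functional and 14 of cell type markers, the comparisons, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The functional lists cover TGF-beta ligands, receptors and Smads, TGF-beta and BMP response genes, extracellular matrix, matrix proteases, pro-inflammatory mediators, anti-inflammatory and reparative genes, resident cardiac macrophages, classical monocytes, efferocytosis, interferon response, cell cycle, glycolysis and hypoxia, oxidative phosphorylation and TCA cycle, MHC class II and co-stimulation, PPAR and LXR lipid handling, and dissociation and immediate early genes. The marker lists cover macrophages, neutrophils, dendritic, B, T, NK and mast cells, cardiomyocytes, fibroblasts, endothelial, mural, mesothelial and erythroid cells, and X-inactivation with Y-linked genes. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, each Benjamini-Hochberg adjusted over the 30 lists of a contrast. Member counts are given over all genes tested and, where they differ, adjusted over the list alone.

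Genes were named by a fixed rule: Smad7 and Lyz2 in each genotype comparison, the 6 higher and 6 lower genes with the largest changes among called genes with an average log2 CPM of at least 1 and non-overlapping groups (predicted genes left out), the 2 called members of each functional list with the lowest p, and, where fewer than 5 genes were called, the 5 lowest p-values as values that did not pass. Genes named outside this rule, among them the members that passed only when adjusted over the list alone, were chosen after their values were seen. Where any library of the lower group held 3 counts or fewer of a gene, levels are given in place of a fold.

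Alternatives were RLE scaling, no low-count filter, DESeq2 1.42.0, limma-voom with sample quality weights, fits of only the groups compared, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM, the same with no filter, a block for the replicate number, and each library left out in turn. Sex as a covariate, read from Xist and 4 Y-linked genes, was added after the data were seen. So was removal of libraries with a minor sex signal over 2%, all of day 3. Replicate numbers did not pair the samples: residual correlations of same-numbered libraries ran from -0.444 to 0.369, and the own number was the best match in 4 of 10. All 35 pairs of libraries in 1 group differed by more than counting error (chi-square per degree of freedom 8.47 to 50.5).

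The tests were run on 13479 genes simulated from the fitted levels and spreads, 50 given each true fold. Of the 1.5-fold changes by genotype edgeR recovered 32, 56 and 36% at baseline, day 3 and day 7. Of 2-fold changes it recovered 52, 74 and 72%, and of 4-fold changes 88, 96 and 92%. False calls made up 4.14, 6.04 and 2.67% of its calls, 8.07, 13 and 6.94% with DESeq2 and 9.62, 7.18 and 2.76% with limma-voom. These rates may not hold for libraries that share structure.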

Results

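Gene expression was profiled by sequencing poly(A) RNA of cardiac macrophages from C57BL/6 mice, sorted magnetically as cells that lacked the neutrophil antigen Ly6G and carried CD11b. Controls (S7fl/fl) had loxP sites in Smad7, which encodes an inhibitory Smad that restrains TGF-beta signalling. Their MyS7KO littermates also carried Cre recombinase in the locus of Lyz2, which encodes lysozyme M and is active in myeloid cells. Cells came from hearts at baseline and from infarcted hearts 3 or 7 days after permanent coronary ligation. The 6 groups held 3 S7fl/fl libraries (16.5 to 21 M counts) and 3 MyS7KO libraries (16.4 to 18.3 M) at baseline, 5 S7fl/fl (15.5 to 20.5 M) and 5 MyS7KO (17 to 23.9 M) at day 3, and 3 S7fl/fl (18 to 19.5 M) and 4 MyS7KO (16.6 to 20.2 M) at day 7. The labels do not say that each sample came from a separate heart, so the p-values measure the spread between these samples. Levels are CPM (counts scaled to the library total with TMM factors), as mean ± SD over libraries, and log2 changes carry their standard error after ±.

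**Figure D1:**
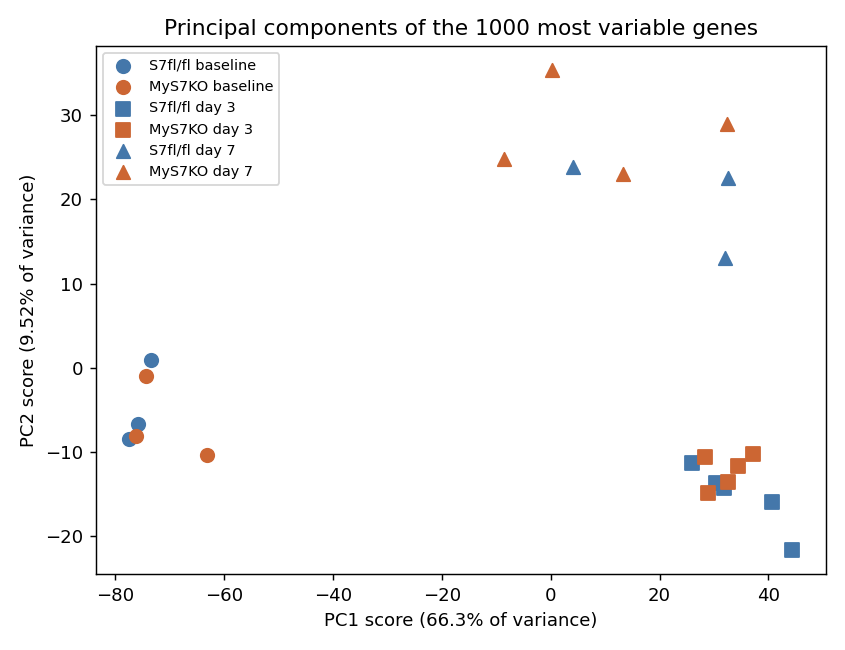
Principal components of the 1000 genes that varied most, with the first component (66.3% of the variance) on the x axis, the second (9.52%) on the y axis and 1 point per library in the 6 groups. Baseline libraries lie between -77.5 and -63.1 on the first component and day 3 libraries between 25.9 and 44.4.

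Time after infarction separated the libraries on the first pair of components. Day 7 libraries lay at -8.55 to 32.6 on the first, and at 13.1 to 35.4 on the second against -21.7 to -10.3 at day 3. Xist, the RNA that silences an X chromosome in female cells, was read in 12 libraries and Y-linked genes in the other 11. The third component was negative in the former (-19.5 to -1.38) and positive in the latter (5.15 to 19.3). At baseline 1 of 3 MyS7KO and 2 of 3 S7fl/fl libraries carried Xist, and at day 3 these were 3 of 5 and 2 of 5. At day 7 all 4 MyS7KO libraries carried Xist and all 3 S7fl/fl libraries carried Y-linked reads. Sex and genotype cannot be told apart at that time, even with sex as a covariate.

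The comparison of MyS7KO with S7fl/fl at baseline asked how macrophages of the uninjured heart differ between the genotypes. Lyz1 (lysozyme P, a paralogue of Lyz2 that also cleaves bacterial cell walls) rose 3.69-fold, to 342 ± 127 CPM (n = 3) from 92.7 ± 41.6 (n = 3; log2 1.88 ± 0.257, edgeR adjusted p = 0.00627). Lyz2 itself, the carrier of the Cre insertion, fell 1.87-fold, to 2852 ± 459 from 5324 ± 368 CPM (log2 -0.90 ± 0.145, edgeR adjusted p = 0.019). Smad7 read 19.7 to 48.7 CPM in the 3 MyS7KO libraries and 53.1 to 61.2 in the 3 S7fl/fl libraries, a 1.49-fold lower mean that did not pass (log2 -0.57 ± 0.282, edgeR adjusted p = 0.999). The labels do not say which part of Smad7 is deleted, so reads from exons outside it stay in this count. Lyz1 lies next to Lyz2 on chromosome 10.

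Lyz1 and Lyz2 were the only genes called of 16545 tested at baseline, 1 higher and 1 lower, where 375 had an unadjusted p under 0.05 against 827 expected by chance. DESeq2 and limma-voom each called 2 genes. Among the lowest p-values that did not pass were those of Dyrk2, a protein kinase of the DNA damage response (79.3 ± 4.66 CPM in MyS7KO, 54.5 ± 4.18 in S7fl/fl, log2 0.54 ± 0.116, edgeR adjusted p = 0.626), and of Fkbp11, a prolyl isomerase of the secretory pathway (0.367 ± 0.151 and 1.00 ± 0.127 CPM, edgeR adjusted p = 0.999). Both lysozyme calls ended when only the baseline libraries were fitted (edgeR adjusted p = 0.999 for Lyz1 and for Lyz2), and without S7fl/fl baseline replicate 1 (0.16 for Lyz1, 0.265 for Lyz2) or replicate 2 (0.0649 for both). The Lyz2 call alone also ended without S7fl/fl baseline replicate 3 (0.064), MyS7KO baseline replicate 1 (0.478) or 2 (0.771), and without the libraries of mixed sex (log2 -0.88, 0.0971).

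By edgeR no member of the 16 functional gene lists was called at baseline, over all genes or adjusted over the list alone. As whole lists, oxidative phosphorylation (respiratory chain and citrate cycle genes) had a lower median of -0.14 (log2; camera adjusted p = 5.82e-05), the interferon response genes -0.31 (camera adjusted p = 0.00769) and the classical monocyte genes -0.26 (0.0345). Pro-inflammatory mediators had a median of 0.08 (camera adjusted p = 0.0417). Among the cell type markers, B cell genes had a median of -0.71 (camera adjusted p = 0.0389) and NK cell genes -0.57 (0.0345). None of these 6 list calls held with an estimated correlation between genes (adjusted p = 0.982 in each case). With sex as a covariate the interferon (-0.17, camera adjusted p = 0.197), monocyte (-0.25, 0.116), B cell (-0.67, 0.116) and NK cell calls (-0.49, 0.142) ended. With no low-count filter the monocyte (camera adjusted p = 0.0746), B cell (0.0932), NK cell (0.0746) and pro-inflammatory calls (0.115) ended. The last also did with RLE scaling (0.0612) and without the libraries of mixed sex (0.10, 0.0551). Each of the 6 ended with 1 library left out. Without MyS7KO baseline replicate 2 these were oxidative phosphorylation (median -0.06, camera adjusted p = 0.0857), interferon response (-0.21, 0.0516), pro-inflammatory mediators (0.07, 0.0912), B cell (-0.56, 0.0934) and NK cell genes (-0.47, 0.0912). Without MyS7KO baseline replicate 3 they were interferon response (-0.22, camera adjusted p = 0.0685), monocyte genes (-0.23, 0.524), pro-inflammatory mediators (0.14, 0.0896), B cell (-0.46, 0.18) and NK cell genes (-0.48, 0.246). Without S7fl/fl baseline replicate 1 they were interferon response (-0.36, camera adjusted p = 0.0952), monocyte genes (-0.36, 0.45), B cell (-0.17, 0.787) and NK cell genes (-0.16, 0.982). Pro-inflammatory mediators stood at 0.17 without that library. Without S7fl/fl baseline replicate 2 interferon response stood at -0.02 (camera adjusted p = 0.717), oxidative phosphorylation at -0.06, NK cell genes at -0.87 and pro-inflammatory mediators at 0.26. The pro-inflammatory median turned to -0.10 without S7fl/fl baseline replicate 3 (camera adjusted p = 0.572). The monocyte median was -0.54 without MyS7KO baseline replicate 1.

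The remaining functional lists were not called at baseline. Their median log2 changes were -0.09 for TGF-beta ligands, receptors and Smads, -0.08 for extracellular matrix genes, 0.03 for anti-inflammatory and reparative genes, 0.05 for resident cardiac macrophage genes, 0.04 for efferocytosis genes, -0.04 for MHC class II genes, -0.03 for PPAR and LXR lipid handling genes and 0.03 for immediate early genes (camera adjusted p = 0.224 to 0.957). TGF-beta and BMP response genes (-0.00), matrix proteases (-0.04), cell cycle genes (-0.02), glycolysis genes (-0.01) and neutrophil markers (-0.01) had medians and camera tests of opposite sign, without a call. Markers of other cells had medians of -0.02 (macrophage), -0.13 (dendritic cell), -0.30 (T cell), -0.35 (mast cell), -0.27 (cardiomyocyte), -0.15 (fibroblast), -0.24 (endothelial), -0.28 (mural), -0.19 (mesothelial) and -0.17 (erythroid). The X-inactivation and Y-linked markers stood at 1.01. Several passed with 1 library left out (camera adjusted p = 0.00369 to 0.0419). Without MyS7KO baseline replicate 1 these were extracellular matrix (-0.34), immediate early (0.17), fibroblast (-0.43), endothelial (-0.47), T cell (-0.63) and X and Y (1.62), and without MyS7KO baseline replicate 2 mesothelial (-1.85), mural (-0.43) and resident macrophage genes (0.18). Without S7fl/fl baseline replicate 2 they were T cell (-0.44) and anti-inflammatory genes (0.10), and without S7fl/fl baseline replicate 3 T cell (-0.53) and X and Y (11.1).

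At day 3 the genotypes were compared in the inflammatory phase of the infarct. Lyz1 rose 7.24-fold, to 75.1 ± 14.3 CPM (n = 5) from 10.4 ± 0.854 (n = 5; log2 2.86 ± 0.215, edgeR adjusted p = 2.78e-07), and Lyz2 fell 1.89-fold, to 3126 ± 189 from 5904 ± 605 CPM (log2 -0.92 ± 0.112, edgeR adjusted p = 0.000229). The Lyz2 call ended without the libraries of mixed sex (log2 -0.84, edgeR adjusted p = 0.0817). Smad7 read 10.5 to 19.9 CPM in the 5 MyS7KO libraries and 30.4 to 42 in the 5 S7fl/fl libraries. This 2.38-fold lower mean did not pass (log2 -1.25 ± 0.227, edgeR adjusted p = 0.11) and passed with DESeq2 (adjusted p = 0.000227), with limma-voom (0.00298), when only the day 3 groups were fitted (edgeR adjusted p = 0.00934), and without MyS7KO day 3 replicate 1 (0.0426).

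Lyz1 and Lyz2 were again the only genes called, with 594 unadjusted p-values under 0.05. DESeq2 and limma-voom each called 4 genes, among them Smad7 and Dyrk2, the kinase next in rank at baseline. Dyrk2 read 82.5 ± 7.64 CPM in MyS7KO and 59.5 ± 4.63 in S7fl/fl (edgeR adjusted p = 0.11, DESeq2 0.00616, limma-voom 0.00298). Lrp2bp, a binding partner of the endocytic receptor megalin, read 0.0865 ± 0.0276 and 0.484 ± 0.194 CPM (edgeR adjusted p = 0.14). It passed without S7fl/fl day 3 replicate 1 (0.0187).

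Among the fixed lists at day 3, edgeR called no functional member over all genes, and adjusted over the list alone only Smad7, a call of DESeq2 and limma-voom over all genes, was lower among 25 TGF-beta ligands, receptors and Smads. That list had a median of -0.07 (camera adjusted p = 0.0148), but holds the targeted Smad7 and was not tested without it. The list call ended without S7fl/fl day 3 replicate 1 (-0.06, 0.051). The median stood at -0.11 without MyS7KO day 3 replicate 1 and -0.04 without replicate 3. Cell cycle genes had a higher median of 0.22 (camera adjusted p = 1.53e-11) and neutrophil markers a lower one of -0.96 (camera adjusted p = 0.00176). The cell cycle median was 0.09 without S7fl/fl day 3 replicate 4, and the neutrophil median -0.47 without S7fl/fl day 3 replicate 2 and -0.49 without replicate 4, each with its call kept. Classical monocyte genes (-0.27, camera adjusted p = 0.00304), MHC class II genes (0.14, 0.0136), immediate early genes (0.11, 0.00436) and cardiomyocyte markers (0.32, 0.0299) were also called. None of these 7 calls held with an estimated correlation. With it the adjusted p was 0.812 for immediate early genes, 0.816 for cardiomyocyte markers and 0.64 for the others. Without the libraries of mixed sex only the cell cycle call held. The others were then TGF-beta (-0.04, camera adjusted p = 0.0647), monocyte (-0.09, 0.405), MHC class II (0.09, 0.23), immediate early (0.08, 0.0647), neutrophil (-0.58, 0.0773) and cardiomyocyte (0.12, 0.338). The monocyte call ended without S7fl/fl day 3 replicate 4 (-0.13, camera adjusted p = 0.212). The MHC class II call ended without S7fl/fl day 3 replicate 1 (0.11, 0.106), MyS7KO day 3 replicate 2 (0.07, 0.104) or replicate 5 (0.11, 0.0658). The immediate early call ended without MyS7KO day 3 replicate 3 (0.05, camera adjusted p = 0.108) or S7fl/fl day 3 replicate 3 (0.11, 0.0692). Its median was 0.17 without MyS7KO day 3 replicate 1 and 0.18 without S7fl/fl day 3 replicate 5. The cardiomyocyte call ended without MyS7KO day 3 replicate 1 or 3 or S7fl/fl day 3 replicate 3 or 4 (0.19 to 0.28, camera adjusted p = 0.106 to 0.184), and with RLE scaling (0.0501). The median stood at 0.54 without S7fl/fl day 3 replicate 5.

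The other lists were not called at day 3. Functional medians were 0.03 for TGF-beta and BMP response genes, 0.17 for extracellular matrix genes, -0.10 for matrix proteases, -0.09 for pro-inflammatory mediators, -0.15 for resident macrophage genes, 0.02 for interferon response genes, -0.08 for glycolysis, 0.04 for oxidative phosphorylation and -0.03 for PPAR and LXR lipid handling genes. The medians of anti-inflammatory genes (0.02), efferocytosis genes (0.02) and T cell markers (0.09) had the opposite sign of their tests. Marker medians were -0.04 (macrophage), 0.20 (dendritic cell), -0.04 (B cell), 0.22 (NK cell), 0.46 (mast cell), 0.21 (fibroblast), 0.15 (endothelial), 0.13 (mural), 0.02 (mesothelial), -0.42 (erythroid) and -0.84 (X and Y). Of these, resident macrophage genes passed without the libraries of mixed sex (-0.23, camera adjusted p = 0.00412), extracellular matrix (0.24, 0.0454) and glycolysis (-0.09, 0.0368) with sex as a covariate, oxidative phosphorylation with RLE scaling (0.0388) or no filter (0.00357), and dendritic cell markers with no filter (0.0484). With 1 library left out more passed (camera adjusted p = 0.00182 to 0.0493). Extracellular matrix and fibroblast markers did so without S7fl/fl day 3 replicate 1 (0.39 and 0.41) or replicate 2 (0.26 each) or MyS7KO day 3 replicate 5 (0.27 and 0.30), and endothelial (0.31) and pro-inflammatory genes (-0.16) without S7fl/fl day 3 replicate 1. Interferon response passed without S7fl/fl day 3 replicate 4 (0.16) or MyS7KO day 3 replicate 1 (0.08). Single leave-outs also gave calls for resident macrophage, glycolysis, oxidative phosphorylation and dendritic cell lists.

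At day 7, when repair follows inflammation, Pf4 joined the lysozymes. Pf4, a chemokine of platelets that resident macrophages also express, fell 2.30-fold in MyS7KO, to 162 ± 34.8 CPM (n = 4) from 372 ± 107 (n = 3; log2 -1.20 ± 0.196, edgeR adjusted p = 0.0179). Lyz1 rose 6.45-fold, to 103 ± 7.36 from 15.9 ± 2.38 CPM (log2 2.69 ± 0.263, edgeR adjusted p = 2.89e-05), and Lyz2 fell 1.95-fold, to 4088 ± 382 from 7990 ± 1490 CPM (log2 -0.97 ± 0.133, edgeR adjusted p = 0.00177). The Lyz2 call ended with only the day 7 groups fitted (0.308). Smad7 read 16 to 33.4 CPM in the 4 MyS7KO libraries and 57.4 to 70.2 in the 3 S7fl/fl libraries. This 2.67-fold lower mean did not pass (log2 -1.42 ± 0.264, edgeR adjusted p = 0.0702) and passed with DESeq2 (adjusted p = 0.000232), limma-voom (0.0187) and limma on log2(FPKM + 1) (0.0344), as well as without MyS7KO day 7 replicate 3 (0.0445) or replicate 4 (0.0314).

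**Figure D2:**
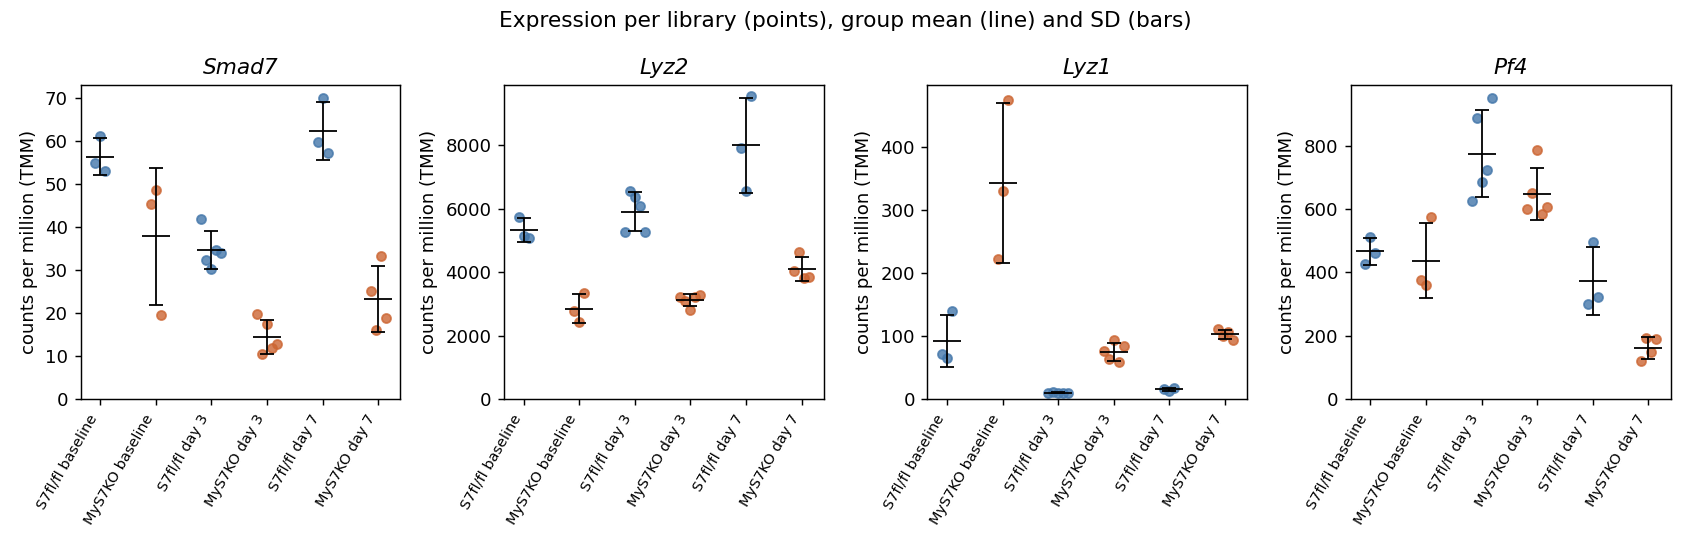
Levels of Smad7, Lyz2, Lyz1 and Pf4 in CPM on the y axis against time on the x axis, with 1 point per library, a line at the mean and bars of 1 SD for each genotype. Lyz1 is higher and Lyz2 lower in MyS7KO at each time.

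Those 3 genes, 1 higher and 2 lower, were the only ones edgeR called at day 7, although 2173 had an unadjusted p under 0.05. DESeq2 called 49 genes (21 higher, 28 lower), limma-voom 13 (5 higher, 8 lower) and limma on log2 FPKM 8 (5 higher, 3 lower). The count rose to 59 without MyS7KO day 7 replicate 3, to 10 without S7fl/fl day 7 replicate 4 and to 6 without S7fl/fl day 7 replicate 2. The Pf4 call ended without MyS7KO day 7 replicate 1 (edgeR adjusted p = 0.12) or 4 (0.097) or S7fl/fl day 7 replicate 3 (0.24). It ended with no filter (0.0759), only the day 7 groups fitted (0.465) or limma on log2(FPKM + 1) and no filter (0.117). It also ended with sex as a covariate (log2 -1.155, 0.118) and without the libraries of mixed sex (log2 -1.183, 0.0634). Just short of passing by edgeR were Cd109, a co-receptor that dampens TGF-beta signalling (means of 23.7 CPM in MyS7KO and 13.7 in S7fl/fl, log2 0.79 ± 0.151, edgeR adjusted p = 0.0702), and Nt5dc2, a putative nucleotidase (49.2 ± 7.33 and 75.8 ± 11.6 CPM, log2 -0.63 ± 0.12, edgeR adjusted p = 0.0702). Cd109 passed with DESeq2 (0.000232), limma-voom (0.0187) and limma on log2(FPKM + 1) (0.0344), and without MyS7KO day 7 replicate 3 (0.028). Nt5dc2 passed with DESeq2 (0.00428) and limma-voom (0.0187), and without MyS7KO day 7 replicate 3 (0.0186) or S7fl/fl day 7 replicate 4 (0.0272).

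Inflammatory, reparative and monocyte lists were lower in MyS7KO at day 7, as were macrophage markers, with stromal markers higher. A shared source was not tested. Of 24 pro-inflammatory mediators edgeR called none over all genes. Adjusted over the list alone 1 was higher and 3 lower, named after their values were seen. DESeq2 called Ccl7 and Nos2 over all genes, and edgeR Ccl7 with the sex covariate estimated at other times. The lower ones were the monocyte chemoattractants Ccl7 (138 ± 20.9 CPM in MyS7KO, 332 ± 126 in S7fl/fl) and Ccl2 (161 ± 25.6 and 287 ± 93.8 CPM) and the interleukin subunit Il23a (log2 -1.52 ± 0.439), while nitric oxide synthase Nos2 had a higher mean (32.7 ± 52.3 and 3.25 ± 1.46 CPM) carried by MyS7KO day 7 replicate 4 alone (111 CPM, 1.21 to 11.2 in the other 3). The list median was -0.36 (camera adjusted p = 4.48e-05; adjusted p = 0.459 with an estimated correlation), and -0.17 without S7fl/fl day 7 replicate 3. Anti-inflammatory and reparative genes had a median of -0.25 (camera adjusted p = 0.00129; adjusted p = 0.251 with an estimated correlation). Adjusted over that list alone, haem oxygenase Hmox1 (log2 -1.03 ± 0.259) and the cytokine Il10 (log2 -1.13 ± 0.295) were lower, both calls of DESeq2 over all genes and Hmox1 also of limma-voom. Classical monocyte genes had a median of -0.33 (camera adjusted p = 0.000808; adjusted p = 0.451 with an estimated correlation), with the chemokine receptor Ccr2 (187 ± 32.1 and 303 ± 21.1 CPM) lower over the list alone and by DESeq2 over all genes.

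Proliferation and energy lists were lower as well. Cell cycle genes had a median of -0.26 (camera adjusted p = 4.7e-05; adjusted p = 0.487 with an estimated correlation, and -0.02, 0.94, with sex as a covariate), and of -0.10 without S7fl/fl day 7 replicate 3. Glycolysis genes stood at -0.20 and oxidative phosphorylation at -0.19 (camera adjusted p = 0.00149 and 8.12e-06, and 0.487 and 0.451 with an estimated correlation). Without MyS7KO day 7 replicate 1 these medians were -0.13 and -0.11. Resident cardiac macrophage genes, of which edgeR called only Pf4, had a median of -0.18 (camera adjusted p = 0.0234, and 0.487 with an estimated correlation). That call ended without S7fl/fl day 7 replicate 2 (-0.04, 0.426), MyS7KO day 7 replicate 4 (-0.17, 0.163) or replicate 5 (-0.08, 0.238), and with sex as a covariate (-0.00, 0.56). Macrophage markers, of which edgeR called only Lyz2, had a median of -0.21 (camera adjusted p = 0.00077, and 0.451 with an estimated correlation). The median was -0.13 without MyS7KO day 7 replicate 1, and -0.16 without the Cre carrier Lyz2, where camera was not rerun.

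Matrix and stromal medians were higher in MyS7KO at day 7, but stromal levels overlapped and edgeR called no member. MyS7KO day 7 replicate 3 had lower mean endothelial (17.5) and mural levels (5.4) than any S7fl/fl library (lowest 20.6 and 6.4). Exact permutation p was 0.2 to 0.314 for the 3 marker lists. Medians were 0.75 for extracellular matrix genes (camera adjusted p = 2.12e-05), 0.74 for fibroblast (0.000237), 0.98 for endothelial (5.89e-05) and 1.22 for mural markers (5.06e-05). With an estimated correlation the adjusted p was 0.487, 0.487, 0.459 and 0.451. Without MyS7KO day 7 replicate 1 extracellular matrix stood at 0.47 and fibroblast markers at 0.45, and without S7fl/fl day 7 replicate 2 at 1.19 and 1.14. Fibroblast markers stood at 0.46 without S7fl/fl day 7 replicate 3. Without MyS7KO day 7 replicate 4 endothelial markers stood at 0.44 and mural markers at 0.69. All 4 calls held in each case. Adjusted over the list alone, 3 of 9 mural genes were higher, namely the pericyte proteoglycan Cspg4 (19.05 ± 3.12 CPM in MyS7KO, 11.0 ± 1.91 in S7fl/fl), the growth factor receptor Pdgfrb (31.9 ± 14.1 and 14.3 ± 7.41 CPM) and Notch3 (log2 1.26 ± 0.461). TGF-beta ligands, receptors and Smads had a median of 0.25 (camera adjusted p = 0.0015; adjusted p = 0.451 with an estimated correlation), with the BMP receptor Bmpr2 higher (97.3 ± 7.12 and 78.8 ± 5.22 CPM) and Smad7 lower over the list alone. Immediate early genes stood at 0.27 (camera adjusted p = 0.0015, and 0.487 with an estimated correlation). That call ended without MyS7KO day 7 replicate 4 (0.18, 0.0519) or 5 (0.13, 0.129).

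Blood and sex markers differed as well at day 7. Erythroid genes had a median of -3.03 (camera adjusted p = 0.019; adjusted p = 0.487 with an estimated correlation), with all 5 lower over the list alone, among them the globin Hbb-bs (4.42 ± 3.61 CPM in MyS7KO, 39.0 ± 63.9 in S7fl/fl, of which replicate 2 read 113 and the others 1.84 and 2.38). Without S7fl/fl day 7 replicate 2 this median turned to 0.93 (camera adjusted p = 0.416). The call ended without MyS7KO day 7 replicate 3 (-2.69, 0.137) or with sex as a covariate (-2.76, 0.137). The X and Y markers stood at -11.3 (camera adjusted p = 0.00233; adjusted p = 0.383 with an estimated correlation), with Xist higher and the 4 Y-linked genes lower over the list alone, and by DESeq2 over all genes. With sex as a covariate this list call ended (-4.49, camera adjusted p = 0.0723). Lists without a call were interferon response (-0.04), MHC class II (-0.14), neutrophil (-0.09), T cell (0.41), mast cell (0.29), cardiomyocyte (0.27) and mesothelial (0.75). Of these, interferon response (-0.29, camera adjusted p = 0.000184) and MHC class II (-0.23, 0.0139) passed with sex as a covariate, and T cell markers with no filter (0.0253). Interferon response turned with the library left out, passing at 0.16 without MyS7KO day 7 replicate 3 (camera adjusted p = 0.0333), -0.13 without replicate 4 (0.0194) and -0.25 without replicate 5 (0.00169). Cardiomyocyte markers passed without S7fl/fl day 7 replicate 2 (1.11, camera adjusted p = 0.000684) or MyS7KO day 7 replicate 3 (0.53, 0.0175), MHC class II without MyS7KO day 7 replicate 4 (-0.22, 0.0254) or S7fl/fl day 7 replicate 3 (-0.17, 0.0359), and T cell markers without S7fl/fl day 7 replicate 4 (0.69, 0.0284). Medians and tests had opposite signs for TGF-beta and BMP response genes (0.00), matrix proteases (-0.06), efferocytosis genes (-0.00), PPAR and LXR lipid handling genes (-0.04) and dendritic cell (0.03), B cell (0.04) and NK cell markers (0.00).

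**Figure D3:**
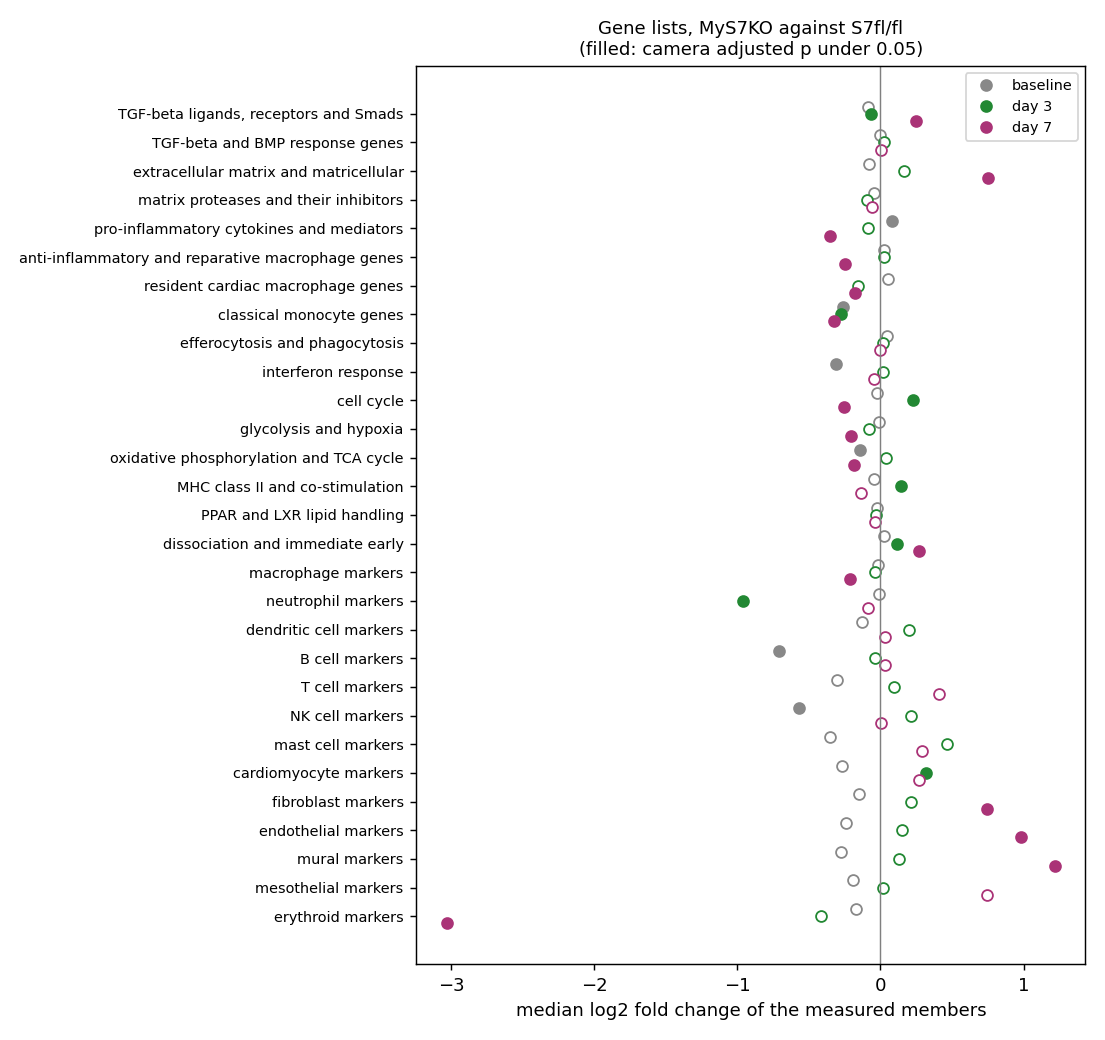
Median log2 fold change of MyS7KO against S7fl/fl on the x axis for 29 gene lists on the y axis (the X and Y list is left out), with 1 point per time, filled where the camera adjusted p is under 0.05. Mural markers reach 1.22 and extracellular matrix genes 0.75 at day 7, and neutrophil markers -0.96 at day 3.

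Whether the genotype effect itself changed with time was asked of each gene. No gene passed in any of the 3 contrasts, with unadjusted p under 0.05 for 741 (day 3 against baseline), 862 (day 7 against baseline) and 1726 genes (day 7 against day 3) by edgeR. DESeq2 called 0, 3 and 3 genes, and limma-voom 0, 0 and 0. Cd109 came closest between day 7 and baseline (log2 difference 1.19 ± 0.228, edgeR adjusted p = 0.435, DESeq2 0.0069), and the antibody segment Ighv1-18 passed with DESeq2 alone between day 7 and day 3 (0.0146; edgeR 0.416). The Smad7 differences of -0.68, -0.84 and -0.16 did not pass (edgeR adjusted p = 0.878, 0.877 and 0.876).

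In S7fl/fl hearts the step from baseline to day 3 asked what infarction does to the macrophage pool. Spp1 (osteopontin, a matricellular cytokine of macrophages) rose 449-fold, to 10990 ± 2290 CPM (n = 5) from 24.4 ± 7.67 (n = 3; edgeR adjusted p = 5.41e-14). Arg1, the arginase of wound-healing macrophages, rose 751-fold (896 ± 501 from 1.17 ± 0.239 CPM, edgeR adjusted p = 1.3e-08). Gpnmb, a glycoprotein of phagocytes, rose 85.2-fold (1249 ± 230 from 14.6 ± 2.58 CPM), the coagulation factor F7 102-fold (78.7 ± 16.3 from 0.759 ± 0.0892 CPM) and the podoplanin gene Pdpn 84.8-fold (416 ± 59.8 from 4.91 ± 0.43 CPM). Prss46, a serine protease gene, reached 2.49 ± 0.737 CPM from 0.0189 ± 0.0327, too few counts for a fold. Among the falls were the resistin-like Retnla 221-fold (1.37 ± 0.847 from 299 ± 98.5 CPM) and the phospholipase Pla2g2d 157-fold (0.422 ± 0.226 from 66.9 ± 13.4 CPM). Langerin Cd207 fell to 0.180 ± 0.0622 from 88.6 ± 46.7 CPM, the lectins Cd209f to 0.201 ± 0.0788 from 34.0 ± 5.28 and Cd209g to 0.0244 ± 0.0335 from 11.0 ± 1.8 CPM, too few counts for a fold.

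In all, 4941 genes rose and 5648 fell at day 3, 10589 of 16545 tested (64%), of which 1698 and 3814 changed at least 2-fold by edgeR. DESeq2 called 10977 and limma-voom 10858. Smad7 fell 1.62-fold (log2 -0.70 ± 0.248, edgeR adjusted p = 0.0185), and Tgfb1, which encodes the main TGF-beta ligand, rose 1.56-fold (edgeR adjusted p = 0.000495).

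Cell identity lists moved at day 3. Of 15 classical monocyte genes 14 rose and none fell, among them the chemokine receptor Ccr2 (3.58-fold, 356 ± 76.6 CPM; median 1.92, camera adjusted p = 7.39e-07; adjusted p = 0.113 with an estimated correlation). Of 18 resident cardiac macrophage genes 16 fell, among them the phosphatidylserine receptor Timd4 (33.9-fold, to 2.67 ± 1.43 from 89.5 ± 12.6 CPM) and the folate receptor Folr2 (4.76-fold), and 1 rose (median -1.27, camera adjusted p = 7.72e-07; adjusted p = 0.113 with an estimated correlation). MHC class II and co-stimulation genes fell in 9 of 15 and rose in 3 (10 and 3 adjusted over the list alone), with the antigen presentation gene H2-Eb1 3.42-fold lower and the lysosomal reductase Ifi30 3.56-fold higher. Their median was -0.71 (camera adjusted p = 0.0292; adjusted p = 0.448 with an estimated correlation). The MHC class II call ended without S7fl/fl day 3 replicate 1 (0.0578).

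Metabolism and proliferation rose at day 3. All 26 oxidative phosphorylation genes rose, among them malate dehydrogenase Mdh2 (2.42-fold) and citrate synthase Cs (1.89-fold; median 0.76, camera adjusted p = 1.34e-08; adjusted p = 0.239 with an estimated correlation). Of 24 glycolysis and hypoxia genes 23 rose, among them the glycolytic enzymes Pgam1 (7.25-fold) and Pkm (5.91-fold; median 1.86, camera adjusted p = 2.19e-18; adjusted p = 0.113 with an estimated correlation). Of 30 cell cycle genes 29 rose, among them the replication helicase subunit Mcm5 (2.73-fold) and cyclin Ccne1 (4.25-fold; median 1.19, camera adjusted p = 1.35e-06; adjusted p = 0.448 with an estimated correlation). PPAR and LXR lipid handling genes rose in 13 of 25 and fell in 5, with the lipid carrier Fabp5 21.1-fold higher and the LDL receptor ligase Mylip 3.89-fold lower (median 0.83, camera adjusted p = 0.0125; adjusted p = 0.216 with an estimated correlation). Immediate early and heat shock genes fell in 23 of 24, among them the transcription factors Atf3 (6.49-fold, to 363 ± 26.1 from 2356 ± 206 CPM) and Jun (7.77-fold; median -1.84, camera adjusted p = 6.19e-16; adjusted p = 0.113 with an estimated correlation).

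Inflammation and matrix turnover rose in part. Of 25 matrix proteases and their inhibitors 16 rose and 5 fell, among them the sheddase Adam8 (28.8-fold) and cathepsin Ctsd (12.3-fold). This list call held with an estimated correlation (median 1.54, camera adjusted p = 6.36e-08; adjusted p = 0.0223 with an estimated correlation). Pro-inflammatory mediators rose in 13 of 24 and fell in 5, with the prostaglandin synthase Ptgs2 19.6-fold and the neutrophil chemokine Cxcl1 3.85-fold higher (median 0.81, camera adjusted p = 0.0125; adjusted p = 0.602 with an estimated correlation; 1.23 without S7fl/fl baseline replicate 1). Anti-inflammatory and reparative genes rose in 14 of 25 and fell in 8, with galectin Lgals3 10.1-fold higher and the lectin Mgl2 17.6-fold lower (median 0.64, camera adjusted p = 0.00917; adjusted p = 0.127 with an estimated correlation). TGF-beta ligands, receptors and Smads fell in 17 of 25 and rose in 4, among the falls the BMP receptor Bmpr1a (7.16-fold) and the endothelial receptor Acvrl1 (1.92-fold; median -0.60, camera adjusted p = 0.0258; adjusted p = 0.448 with an estimated correlation).

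Lists without a call at day 3 still held called members. TGF-beta and BMP response genes rose in 6 of 22, with thrombospondin Thbs1 29.1-fold and the matrix protein Tgfbi 3.12-fold higher, and fell in 10 (11 adjusted over the list alone; median -0.19). Extracellular matrix genes rose in 5 and fell in 9 of 28 (median -0.22, of opposite sign to its test). Efferocytosis genes rose in 10 (11 over the list alone) and fell in 10 of 26, with the lipid receptor Trem2 5.38-fold higher (median 0.17). Interferon response genes rose in 7 of 30 (6 over the list alone) and fell in 3, with the signal transducer Stat2 1.98-fold and the antiviral Mx2 2.79-fold lower (median 0.15).

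Markers of other cell types mostly fell at day 3. All 9 mural genes fell (Myh11 19.6-fold, to 27.5 ± 8.59 from 540 ± 89.7 CPM; median -2.39, camera adjusted p = 0.00108; adjusted p = 0.418 with an estimated correlation), as did all 10 endothelial genes (median -2.20, camera adjusted p = 0.00494; adjusted p = 0.527 with an estimated correlation). The same held for all 11 cardiomyocyte genes (-2.23, camera adjusted p = 0.00439; adjusted p = 0.448 with an estimated correlation), all 7 NK cell genes (-2.96, camera adjusted p = 0.0033; adjusted p = 0.404 with an estimated correlation) and all 7 B cell genes (-2.23, camera adjusted p = 0.0264; adjusted p = 0.399 with an estimated correlation; -1.41 without S7fl/fl baseline replicate 1). All 3 T cell genes fell (-1.89, camera adjusted p = 0.0339; adjusted p = 0.25 with an estimated correlation), a list call that ended without S7fl/fl baseline replicate 2 (0.07). Fibroblast markers fell in 6 of 11 (median -1.37), mesothelial in 2 of 3 (-2.02) and erythroid in all 5 (-3.16), without a list call, although the fibroblast list passed with no filter (camera adjusted p = 0.0328). Macrophage markers rose in 3 and fell in 5 of 11 (-0.23) and mast cell markers rose in 1 and fell in 1 of 2 (-1.33), both medians with the opposite sign of their tests. Neutrophil markers rose in 1 and fell in 4 of 11 (3 over the list alone; -0.62), dendritic cell markers rose in 3 and fell in 4 of 8 (-0.58), and X and Y markers stood at 0.65 without a called member.

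The comparison of day 7 with baseline in S7fl/fl asked which of these shifts were present in the repair phase. Spp1 stood 195-fold above baseline (4761 ± 1470 CPM, n = 3, edgeR adjusted p = 6.55e-13), Arg1 254-fold (303 ± 79.5 CPM, edgeR adjusted p = 2.39e-07) and Gpnmb 104-fold (1520 ± 819 CPM). The lysosomal channel Mcoln3 (7.30 ± 4.05 from 0.0938 ± 0.0169 CPM, n = 3 each), Prss46 (4.69 ± 0.818 CPM) and Shisa9 (4.25 ± 0.852 from 0.0428 ± 0.0741 CPM) rose from too few baseline counts for a fold. The B cell chemokine Cxcl13 fell 78.9-fold (0.706 ± 0.434 from 57.0 ± 32 CPM) and Cd207 73.6-fold (1.20 ± 0.352 CPM). Too few counts for a fold were left of the cytokine-like Cytl1 (0.206 ± 0.218 from 35.7 ± 8.58 CPM), Cd209f (0.330 ± 0.29 CPM), the natriuretic peptide receptor Npr3 (0.130 ± 0.0798 from 13.1 ± 4.21 CPM) and the sodium channel subunit Scn4b (0.0928 ± 0.112 from 8.29 ± 2.65 CPM), which fell as well. Smad7 did not differ from baseline (log2 0.15, edgeR adjusted p = 0.685), while Tgfb1 stood 1.60-fold higher (edgeR adjusted p = 0.00121). By edgeR 4105 genes rose and 4199 fell, 8304 of 16545 (50.2%), of which 1353 and 2800 changed at least 2-fold, and DESeq2 called 8364 and limma-voom 8746.

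TGF-beta response genes, matrix genes and matrix proteases stood above baseline as lists at day 7. The type I receptor Tgfbr1 rose 2.74-fold, to 516 ± 35 from 188 ± 32.3 CPM (edgeR adjusted p = 2.85e-08), although 14 of 25 TGF-beta ligands, receptors and Smads fell and 5 rose (median -0.40, not called). TGF-beta and BMP response genes rose in 11 of 22 and fell in 4, with the corepressor Tgif1 2.43-fold and Thbs1 11.4-fold higher (median 0.55, camera adjusted p = 0.0227; adjusted p = 0.29 with an estimated correlation). That call ended without S7fl/fl baseline replicate 3 (0.0507) or S7fl/fl day 7 replicate 2 (median 0.32, 0.0787). Extracellular matrix genes rose in 11 of 28 and fell in 3 (median 0.53, camera adjusted p = 0.0255; adjusted p = 0.717 with an estimated correlation). The matrix call ended without S7fl/fl baseline replicate 2 (0.0585) or S7fl/fl day 7 replicate 2 (median 0.03, 0.12), and with sex as a covariate (0.37, 0.0846). Matrix proteases rose in 18 of 25 and fell in 5, with Adam8 15.9-fold and the membrane protease Mmp14 12.8-fold higher, and held with an estimated correlation (median 1.56, camera adjusted p = 7.06e-10; adjusted p = 0.00847 with an estimated correlation).

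Inflammatory and reparative genes were both above baseline at day 7. Anti-inflammatory and reparative genes rose in 14 of 25 and fell in 5, with the angiogenic factor Vegfa 8.12-fold higher, and held with an estimated correlation (median 0.79, camera adjusted p = 1.9e-06; adjusted p = 0.00849 with an estimated correlation). Pro-inflammatory mediators rose in 14 of 24 (15 over the list alone) and fell in 2, with Ptgs2 10.1-fold and oncostatin Osm 4.62-fold higher (median 0.80, camera adjusted p = 0.000624; adjusted p = 0.442 with an estimated correlation). Monocyte genes rose in 7 of 15 (9 over the list alone) with Ccr2 3.04-fold higher (0.96, camera adjusted p = 0.000512; adjusted p = 0.256 with an estimated correlation). Resident macrophage genes fell in 11 of 18 (12 over the list alone) and rose in 2, with Timd4 22.4-fold and Folr2 4.68-fold lower (-0.88, camera adjusted p = 3.8e-05; adjusted p = 0.179 with an estimated correlation). Efferocytosis genes rose in 13 of 26 (14 over the list alone) and fell in 5, with Trem2 8.26-fold and the integrin Itgb5 3.13-fold higher (0.40, camera adjusted p = 0.0197; adjusted p = 0.179 with an estimated correlation). Interferon response genes rose in 5 of 30 (4 over the list alone) and fell in 3, among them Oas2 2.58-fold lower (0.11, not called), and MHC class II genes rose in 5 and fell in 6 of 15 (7 over the list alone), with cathepsin Ctss 4.17-fold higher (-0.26, of opposite sign to its test).

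Energy and proliferation lists stood above baseline at day 7. Glycolysis genes rose in 21 of 24 (over the list alone 1 also fell), with Pgam1 4.52-fold higher (median 1.17, camera adjusted p = 1.48e-11; adjusted p = 0.179 with an estimated correlation). Oxidative phosphorylation genes rose in 17 of 26, with cytochrome oxidase Cox5a 2.14-fold higher (0.45, camera adjusted p = 0.000499; adjusted p = 0.442 with an estimated correlation). Cell cycle genes rose in 22 of 30 (23 over the list alone), with Ccne1 3.14-fold and cyclin Ccnb1 2.61-fold higher (0.74, camera adjusted p = 0.000475; adjusted p = 0.582 with an estimated correlation). PPAR and LXR lipid handling genes rose in 12 of 25 and fell in 4, with Fabp5 11.2-fold and the cholesterol esterifying Soat1 2.84-fold higher (0.44, camera adjusted p = 0.000662; adjusted p = 0.149 with an estimated correlation). Immediate early and heat shock genes fell in 17 of 24, with the chaperones Hsp90aa1 6.17-fold and Dnajb1 6.57-fold lower (-1.16, camera adjusted p = 3.24e-10; adjusted p = 0.179 with an estimated correlation).

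Among markers at day 7, macrophage genes rose in 7 of 11 (median 0.59, camera adjusted p = 0.00463; adjusted p = 0.348 with an estimated correlation). All 9 mural genes (-2.83, camera adjusted p = 6.62e-05; adjusted p = 0.29 with an estimated correlation) and all 10 endothelial genes fell (-2.61, camera adjusted p = 4.84e-05; adjusted p = 0.37 with an estimated correlation). Cardiomyocyte genes fell in 9 of 11 (10 over the list alone; -1.68, camera adjusted p = 0.00905; adjusted p = 0.474 with an estimated correlation; -2.54 without S7fl/fl day 7 replicate 2) and NK cell genes in 6 of 7 (-1.91, camera adjusted p = 0.0179; adjusted p = 0.442 with an estimated correlation), the latter call ending without S7fl/fl day 7 replicate 2 (0.0532). Lists without a call were B cell (2 of 7 fell, -0.38), T cell (2 of 3 fell, -1.35), mesothelial (2 of 3 fell, -2.28) and neutrophil (3 rose and 4 fell of 11, -1.66). Medians and tests had opposite signs for fibroblast (4 rose and 4 fell of 11, -0.19), dendritic cell (3 and 3 of 8, -0.67), mast cell (1 and 1 of 2, -1.06), erythroid (none of 5, 0.70, and -3.12 without S7fl/fl day 7 replicate 2) and X and Y markers (none of 5, 1.49).

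From day 3 to day 7 in S7fl/fl the comparison asked how inflammation passes into repair. Among the rises, Comp, a cartilage matrix protein, rose 18.9-fold, to 32.0 ± 18 CPM (n = 3) from 1.68 ± 0.737 (n = 5; edgeR adjusted p = 2.13e-06). From too few counts for a fold, the short-chain collagen Col8a2 rose to 10.5 ± 5.03 from 0.302 ± 0.372 CPM (edgeR adjusted p = 3.75e-06), the collagen Col11a1 to 12.2 ± 7.73 from 0.440 ± 0.319, the hyaluronidase Cemip to 6.05 ± 3.75 from 0.213 ± 0.16 and C1qtnf3 to 7.40 ± 5.03 from 0.0325 ± 0.0462 CPM. Fibroblast marker means rose too (11.1 to 38.8 at day 3, 43 to 106 at day 7). Carried-over stromal cells as a source were not tested. Among the falls were Amd2, a decarboxylase of polyamine synthesis (to 0.208 ± 0.0617 from 2.91 ± 0.308 CPM, too few counts for a fold), and the collagenase Mmp8 6.80-fold (8.58 ± 3.93 from 58.4 ± 19.9 CPM). Dermokine Dmkn fell 6.19-fold, the chemokine Cxcl5 6.13-fold and the surface antigen Cd177 4.66-fold. Inhba, an activin subunit, fell 5.97-fold (11.6 ± 4.12 from 68.9 ± 46.9 CPM, edgeR adjusted p = 0.0265). That call ended with limma-voom, no filter or no mixed-sex libraries (0.0581 to 0.0746). It also ended without S7fl/fl day 3 replicate 2 or 4, or any S7fl/fl day 7 library (0.0513 to 0.121). Spp1 fell 2.31-fold and Smad7 rose 1.80-fold (log2 0.85 ± 0.248, edgeR adjusted p = 0.018). By edgeR 1909 genes rose and 1678 fell, 3587 of 16545 (21.7%), of which 709 and 143 changed at least 2-fold, and DESeq2 called 3977 and limma-voom 4232. The edgeR count was 2195 without S7fl/fl day 7 replicate 2.

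TGF-beta and BMP response genes, as a list, stood higher at day 7 than at day 3. They rose in 11 of 22 (12 over the list alone) and fell in 2, with the feedback gene Pmepa1 3.34-fold and the early response factor Klf10 1.92-fold higher (median 0.53, camera adjusted p = 1.24e-05; adjusted p = 0.0689 with an estimated correlation). Of 25 ligands, receptors and Smads 5 rose and 1 fell, with Tgfbr1 2.88-fold and Tgfbr2 1.39-fold higher (0.07, not called). That list passed with no filter (camera adjusted p = 0.0207), and without S7fl/fl day 7 replicate 3 (0.18, 0.0406) or replicate 4 (0.23, 0.0488). Extracellular matrix genes rose in 14 of 28 (15 over the list alone) and fell in 5, with thrombospondin Thbs2 6.02-fold and periostin Postn 5.82-fold higher (1.29, camera adjusted p = 0.00822; adjusted p = 0.704 with an estimated correlation). The matrix call ended without S7fl/fl day 7 replicate 2 (median 0.79, 0.118). Matrix proteases rose in 4 and fell in 7 of 25 (5 and 9 over the list alone; -0.20, not called), with the inhibitor Timp2 1.88-fold higher. Fibroblast markers rose in 8 of 11 (9 over the list alone; 1.66, camera adjusted p = 1.71e-05; adjusted p = 0.34 with an estimated correlation).

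Macrophage identity shifted in the same interval. Monocyte genes fell in 10 of 15 (12 over the list alone), with clotting factor F10 4.46-fold lower (median -1.20, camera adjusted p = 6.13e-07; adjusted p = 0.12 with an estimated correlation). Resident macrophage genes rose in 6 of 18 and fell in 2, with the fractalkine receptor Cx3cr1 2.61-fold and the phagocytic kinase Mertk 1.99-fold higher (0.56, camera adjusted p = 0.00894; adjusted p = 0.405 with an estimated correlation; 0.26 without S7fl/fl day 7 replicate 2). MHC class II genes rose in 12 of 15, with H2-Eb1 2.12-fold and H2-Aa 2.11-fold higher (0.64, camera adjusted p = 2.6e-08; adjusted p = 0.0689 with an estimated correlation). Efferocytosis genes rose in 9 of 26 (10 over the list alone) and fell in 3, with the kinase Axl 2.70-fold higher (0.36, camera adjusted p = 0.00162; adjusted p = 0.0689 with an estimated correlation). Macrophage markers rose in 8 of 11 and fell in 1 (2 over the list alone; 0.66, camera adjusted p = 8.41e-05; adjusted p = 0.212 with an estimated correlation). Anti-inflammatory genes rose in 7 of 25 and fell in 2 (9 and 3 over the list alone), with the growth factor genes Pdgfb 2.92-fold and Pdgfa 2.67-fold higher (0.13, camera adjusted p = 0.0329; adjusted p = 0.23 with an estimated correlation). That list call ended without S7fl/fl day 3 replicate 1 (0.0546) or S7fl/fl day 7 replicate 3 (median 0.06, 0.0976).

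Metabolic and cycling lists fell back. Glycolysis genes fell in 17 of 24 (18 over the list alone), with phosphoglycerate kinase Pgk1 2.37-fold and enolase Eno1 1.97-fold lower (median -0.68, camera adjusted p = 2.5e-12; adjusted p = 0.143 with an estimated correlation). Oxidative phosphorylation genes fell in 16 of 26, with Mdh2 1.73-fold and the ATP synthase Atp5b 1.49-fold lower (-0.36, camera adjusted p = 2.6e-08; adjusted p = 0.247 with an estimated correlation). Cell cycle genes fell in 9 of 30, with the helicase subunits Mcm4 1.60-fold and Mcm2 1.85-fold lower (-0.46, camera adjusted p = 0.000168; adjusted p = 0.571 with an estimated correlation). Immediate early genes rose in 12 of 24 (15 over the list alone) and fell in 1, with Atf3 2.23-fold and the signalling brake Socs3 2.27-fold higher (0.69, camera adjusted p = 2.16e-07; adjusted p = 0.247 with an estimated correlation). Pro-inflammatory mediators rose in 6 and fell in 4 of 24, with the chemokine Ccl3 1.90-fold and the interleukin subunit Il12b 2.94-fold higher (-0.13, of opposite sign to its test). PPAR and LXR lipid handling genes rose in 5 and fell in 6 of 25 (6 and 10 over the list alone; 0.08), with the lipid carrier Apoe 2.74-fold higher, and no interferon response gene of 30 was called (0.02, of opposite sign to its test).

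B cell markers rose in 3 of 7 (6 over the list alone), with the antibody heavy chain Ighm 3.73-fold higher (median 1.27, camera adjusted p = 0.00671; adjusted p = 0.247 with an estimated correlation). The B cell call ended without S7fl/fl day 7 replicate 4 (median 0.32, 0.0653). NK cell markers rose in 1 of 7 (3 over the list alone; 1.14, camera adjusted p = 0.0359; adjusted p = 0.552 with an estimated correlation). This call ended without S7fl/fl day 3 replicate 1, 2 or 3 (0.0502 to 0.052) or S7fl/fl day 7 replicate 4 (median 0.53, 0.295). All 5 erythroid genes rose (Hbb-bt to 5.81 ± 9.36 from 0.270 ± 0.244 CPM, of which S7fl/fl day 7 replicate 2 read 16.6 and the other day 7 libraries 0.39 and 0.427) without a list call (4.09). Without S7fl/fl day 7 replicate 2 that median was 0.53 (camera adjusted p = 0.88). The list passed without S7fl/fl day 7 replicate 3 (0.0143) or replicate 4 (0.000831), and with no filter (0.0214). The other markers were not called: neutrophil (3 rose and 1 fell of 11, 6 and 3 over the list alone, 0.63), dendritic cell (2 of 8 rose, 0.18), T cell (1 of 3 rose, 0.48), mast cell (0.27), cardiomyocyte (0.80), endothelial (-0.65) and mural (1 of 9 rose and none over the list alone, -0.44). Of these, T cell markers passed with sex as a covariate (0.70, camera adjusted p = 0.0212), cardiomyocyte markers with no filter (0.0256) or without S7fl/fl day 7 replicate 4 (1.04, 0.0203), and mural markers without S7fl/fl day 7 replicate 2 (-0.93, 0.0462). Endothelial markers passed with no filter (camera adjusted p = 0.0207), without the libraries of mixed sex (0.0417), and without S7fl/fl day 7 replicate 2 (-1.09, 0.00687) or S7fl/fl day 3 replicate 3 (-0.74, 0.0498) or replicate 4 (-0.78, 0.0311). Mesothelial (-0.26) and X and Y markers (0.83) had medians of opposite sign to their tests.

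**Figure D4:**
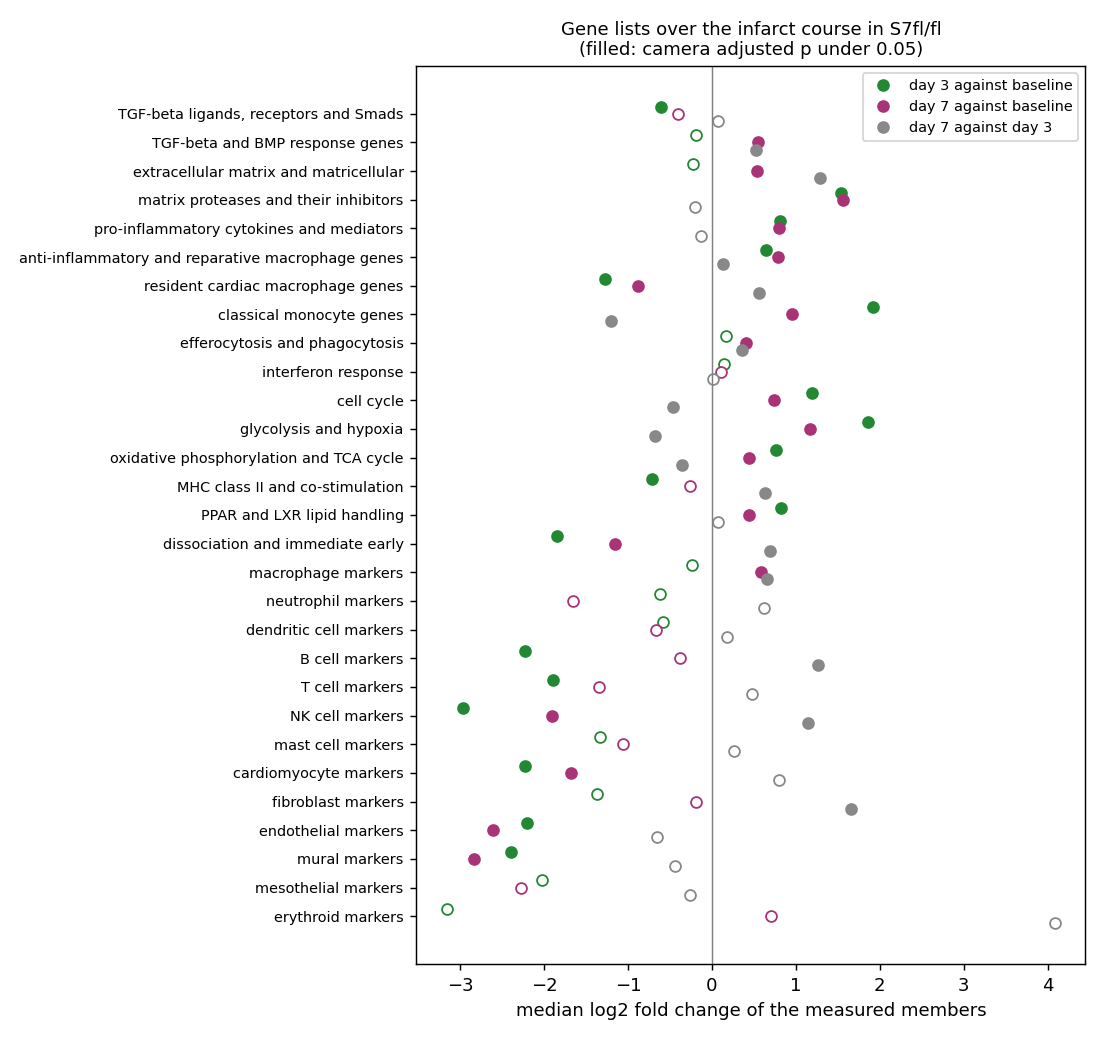
Median log2 fold change in S7fl/fl on the x axis for 29 gene lists on the y axis (the X and Y list is left out), with 1 point per comparison of times, filled where the camera adjusted p is under 0.05. Glycolysis genes stand at 1.86 at day 3 and 1.17 at day 7 against baseline, and immediate early genes at -1.84 and -1.16.

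The MyS7KO course asked whether MyS7KO cells answer the infarct as S7fl/fl cells do. By edgeR 10904 genes changed at day 3 (5081 rose, 5823 fell), 7285 at day 7 (3680 rose, 3605 fell) and 6553 between day 3 and day 7 (3396 rose, 3157 fell). Genes called in both genotypes numbered 9301, all with the same sign, at day 3, 6203, all with the same sign, at day 7, and 2967, of which 2966 had the same sign, between them. Across 12136 genes, which are not independent replicates, the fold changes of the genotypes had r of 0.97, 0.932 and 0.791. Matrix proteases held with an estimated correlation at day 3 (median 1.57; adjusted p = 0.0371 with an estimated correlation) and day 7 (1.57; adjusted p = 0.00235 with an estimated correlation). At day 7 the same was true of anti-inflammatory genes (15 rose and 7 fell of 25, 0.83; adjusted p = 0.034 with an estimated correlation), PPAR and LXR lipid handling genes (14 and 4 of 25, 0.81; adjusted p = 0.034 with an estimated correlation) and resident macrophage genes (2 and 13 of 18, -1.46; adjusted p = 0.0354 with an estimated correlation).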

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

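All tests that weigh an explanation here were chosen only after the result was seen, while the counts over other splits of the libraries had been set before.

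A library far from the others of its group was found in 8 of 126 groups of values, where chance gives about 1 in 20 (6.3). The values were Lrp2bp at 0.148 CPM in S7fl/fl day 3 replicate 1 (others 0.514 to 0.648), Prss46 at 3.77 CPM in S7fl/fl day 3 replicate 5 (1.97 to 2.42), Cx3cr1 at 173.6 CPM in S7fl/fl day 3 replicate 3 (105.5 to 118.4) and Mcm4 at 46.3 CPM in S7fl/fl day 3 replicate 4 (66 to 72.5). In MyS7KO they were Tlr5 at 7.79 CPM in day 3 replicate 5 (13 to 13.6), Prkg1 at 0.298 CPM in day 3 replicate 1 (0.540 to 0.596) and a total of 20.2 M counts in day 7 replicate 5 (16.6 to 16.9). The rRNA share was 0.678% in S7fl/fl day 3 replicate 4 (0.0285 to 0.049 in the others). All were singled out by Dixon's ratio within the group, and at this rate most may be ordinary spread.

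Gene lists whose genotype effect differed between times were singled out by camera, although edgeR called no single gene (DESeq2 called 0, 3 and 3). Between day 3 and baseline the medians of the difference were -0.28 for resident macrophage genes (camera adjusted p = 0.0399), 0.38 for interferon response (0.0139), 0.22 for cell cycle (0.000451), 0.20 for oxidative phosphorylation (0.000123), -0.85 for neutrophil markers (0.0399), 0.73 for NK cell markers (0.0365) and 0.52 for cardiomyocyte markers (0.0365). With an estimated correlation the adjusted p was 0.77 for all 7.

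Between day 7 and baseline, camera singled out TGF-beta ligands, receptors and Smads (0.20, adjusted p = 0.00329), extracellular matrix (0.83, 2.79e-05), pro-inflammatory mediators (-0.49, 9.55e-07), anti-inflammatory genes (-0.0906, 0.000614), resident macrophage genes (-0.29, 0.00326), cell cycle (-0.24, 0.000468), glycolysis (-0.17, 0.00346), immediate early genes (0.24, 0.0309) and macrophage markers (-0.19, 0.0121). Markers of other cells singled out were T cell (0.71, camera adjusted p = 0.011), fibroblast (0.84, 0.000146), endothelial (1.23, 8.77e-06), mural (1.45, 4.83e-06), erythroid (-3.10, 0.0186) and X and Y (-12.30, 0.000468). With an estimated correlation the adjusted p ran from 0.163 to 0.669.

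Between day 7 and day 3 these were TGF-beta ligands, receptors and Smads (0.32, camera adjusted p = 0.000129), extracellular matrix (0.60, 0.00708), pro-inflammatory mediators (-0.33, 0.00356), anti-inflammatory genes (-0.20, 0.00356), cell cycle (-0.43, 4.58e-12), oxidative phosphorylation (-0.22, 1.26e-06) and MHC class II (-0.30, 0.00548). Fibroblast (0.61, camera adjusted p = 0.0402), endothelial (0.79, 0.0121), mural (1.04, 0.00435) and X and Y markers (-10.40, 0.0121) were singled out as well. With an estimated correlation the adjusted p ran from 0.291 to 0.789.

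Lyz1 was higher and Lyz2 lower in MyS7KO at all 3 times. A fixed share of Lyz2 reads counted under Lyz1 is argued against by the sign, since Lyz1 rose by at least 1.88 on the log2 scale where Lyz2 fell, and lost reads counted under Lyz1 are argued against as the cause of the Lyz2 fall by the amount, since Lyz1 gained at most 10.1% of the CPM that Lyz2 lost (250 of 2472 CPM at baseline). Lyz2 reads counted under Lyz1 in MyS7KO may still make the Lyz1 rise, which would need 8.76%, 2.07% and 2.13% of the Lyz2 level at baseline, day 3 and day 7: these shares differ by at most 2.36 standard errors, between bounds of 1 and 3 set after the shares were known, so this stays open. A region around the Cre insertion that differs between the genotypes may contribute: Dyrk2, 1.58 Mb away, was higher and Tbc1d30, 3.99 Mb away, lower at each time at unadjusted p, and 0% of 15492 overlapping windows of 49 neighbouring genes held as many such genes, but that criterion was set after these genes had been seen and cannot decide. No group carried the insertion with intact Smad7 (0 groups), so that Smad7 loss and the insertion cannot be told apart.

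Fibroblast, endothelial and mural markers were higher in MyS7KO at day 7 (median 0.91 over 30 genes). A sex difference of the same size at every time is argued against by the median of -0.18 (jackknife SE 0.277) for Xist against Y-linked libraries among 16 libraries of baseline and day 3, and 1 library setting the difference is argued against by a lowest median of 0.62 (without MyS7KO day 7 replicate 4; highest 1.34, without S7fl/fl day 7 replicate 2). Stromal cells carried over in differing amounts may be a source, since the 3 marker means moved together across 23 libraries less their group means (r 0.717, 0.702 and 0.902, rho 0.754, 0.718 and 0.795, permutation p = 0.00163, 0.00112 and 6e-05, r 0.695, 0.732 and 0.782 without the 2 farthest libraries, and 0.709, 0.716 and 0.901 without the 3 markers seen beforehand). This speaks to libraries within groups, not to genotype: the list means at day 7 differed with exact two-sided permutation p = 0.2, 0.314 and 0.286 over 35 splits (adjusted p = 0.314). A sex effect present only at day 7 stays open.

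Pf4 was lower in MyS7KO at day 7. Dilution of macrophage RNA by other cells is argued against by the median of -0.16 for the 10 macrophage markers other than Lyz2, and a sex difference of the same size at every time by -0.0357 ± 0.118 for Pf4 in Xist libraries at baseline and day 3. Less platelet RNA may contribute and stays open: Ppbp, another platelet chemokine, read 3.64 ± 1.61 CPM in MyS7KO and 27.3 ± 28.3 in S7fl/fl, a loss of 11.3% of that of Pf4, where the bound set for excluding it was under 10%. The other 7 platelet genes tested did not follow Ppbp (Treml1 -0.69, Gp1ba -0.34, Gp9 -0.17, Itga2b -0.05, Gp5 0.03, Clec1b 0.28 and Tubb1 0.52, lowest unadjusted p = 0.119), but all read under 3 CPM.

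Splits of the same libraries into other groups of the same sizes made chance unlikely for most counts by time, which no other split reached. In S7fl/fl these were 10589 genes at day 3 and 3587 between day 7 and day 3 (56 splits each, highest others 4463 and 233). In MyS7KO they were 10904, 7285 and 6553 (56, 35 and 100 splits, highest others 4046, 5087 and 4352). For the 2 genes called by genotype at day 3 chance was made unlikely (2 of 100 splits as high, highest other 4). Too few splits exist to judge the 2 genes at baseline and the 8304 of S7fl/fl at day 7 against baseline (highest other 0 for both). They could not exclude chance for the 3 genes called by genotype at day 7. The split that put MyS7KO day 7 replicate 3 with S7fl/fl day 7 replicates 3 and 4 called 1629. This points to sample structure other than genotype. These 3 libraries lay at 32.4, 32 and 32.6 on the first component and the other day 7 libraries between -8.55 and 13.2. Of the 3 genes, Lyz1 and Lyz2 were also called with the same sign at baseline and at day 3 in other libraries, 2 shared calls with each where 0.000363 were expected if independent, which excludes chance for them and leaves it open for Pf4. The 0 genes called for differences of the genotype effect (highest others 0, 19 and 220) cannot be judged this way.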

How the results depend on the processing

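Sex as a covariate and the removal of libraries with mixed sex signals were tests chosen only after the result was seen, and all others had been fixed before.

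Among values of genes named by genotype, 269 kept their side of the threshold, 24 lost a call and 21 gained one. For genes named by time these were 2156 and 8 lost, and for lists 2199 same, 147 weaker, 79 stronger and 5 reversed. Scaling moved the median of all genes by at most 0.02 on the log2 scale.

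Genes called by genotype moved as follows, and the cause was not tested. At baseline (2 called), none were called with only those groups fitted, 6 with limma on log2(FPKM + 1) (2 higher, 4 lower against 1 and 1), 39 with no filter on that scale (17 higher, 22 lower) and 1 without the libraries of mixed sex. At day 3 (2 called), DESeq2 and limma-voom called 4 and removal of mixed-sex libraries left 1. At day 7 (3 called), DESeq2 called 49, limma-voom 13, limma on log2(FPKM + 1) 8 (5 higher, 3 lower against 1 and 2) and fits of only those groups 5, namely Lyz1 (higher) and the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d (lower), without Lyz2 (0.308) and Pf4 (0.465). For differences between times (0 called), FPKM with no filter gave 15 (day 3 against baseline) and 14 (day 7 against baseline), and DESeq2 gave 3 for each difference with day 7.

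With 1 library left out the genotype counts ranged from 0 to 2 at baseline (0 without S7fl/fl baseline replicate 1 or 2), 2 to 4 at day 3 (4 without MyS7KO day 3 replicate 1) and 2 to 59 at day 7 (59 without MyS7KO day 7 replicate 3). In S7fl/fl they ranged from 9739 to 10379, 7009 to 8155 and 2195 to 3306 (2195 without S7fl/fl day 7 replicate 2), in MyS7KO from 9776 to 10756, 5748 to 7204 and 5414 to 6429, and for the differences from 0 to 0. Lists called ranged from 1 to 12 at baseline (12 without MyS7KO baseline replicate 1, 1 without MyS7KO baseline replicate 3), 6 to 12 at day 3 (12 without S7fl/fl day 3 replicate 1), 15 to 17 at day 7, and 17 to 18, 15 to 18 and 13 to 16 in S7fl/fl.

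An estimated correlation left 0 of the 6, 7 and 16 lists called by genotype and 1, 2 and 0 in S7fl/fl. At baseline no filter left 2 lists and sex as a covariate 2, and at day 3 removal of mixed-sex libraries kept cell cycle alone of the 7 and added resident macrophage genes. The cause was not tested.

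The replicate block, although numbers do not pair the samples, called 1 gene at each of baseline, day 3 and day 7, and 11 lists at day 3. The Lyz2 call ended under the block at each time (edgeR adjusted p = 0.975, 0.0684 and 0.272), as did that of Pf4 at day 7 (0.101). Under the block the day 7 medians reversed to 1.48 for neutrophil markers and 0.81 for erythroid markers. With 1 library left out, the baseline median of pro-inflammatory mediators ran from -0.10 to 0.26. The day 7 median of interferon response ran from -0.25 to 0.16, and that of erythroid markers from -3.6 (without S7fl/fl day 7 replicate 4) to 0.93 (without S7fl/fl day 7 replicate 2). The cause was not tested.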

Other observations

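The tests of sex-linked genes and of mixed sex signals were chosen only after the result was seen.

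Across the 23 libraries 13 genes were called between those with Xist and those with Y-linked reads, 6 higher and 7 lower in the former. Besides Xist and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, the X-linked Kdm6a, Kdm5c and Eif2s3x, which escape inactivation, were among them. The minor signal of the other sex reached 7.92% in S7fl/fl day 3 replicate 4, 2.97% in MyS7KO day 3 replicate 3 and 2.04% in MyS7KO day 3 replicate 2, and no value tells mixed material from carry-over between libraries.

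In libraries of baseline and day 3, Lyz1 was lower in those with Xist (log2 -0.52 ± 0.13) and Lyz2 was not (0.01), while Ccl7 was higher (0.37 ± 0.13) and Smad7 differed little (-0.10 ± 0.174). At day 7, where MyS7KO libraries carried Xist, Lyz1 was higher and Ccl7 lower in MyS7KO, opposite in sign to these differences.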
